A study of Mus musculus with 19 samples.

How the data were processed

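RNA had been extracted from flow-sorted basal, luminal and stromal cells of mouse anterior prostates, amplified with a low-input full-length method, made into libraries by tagmentation and sequenced on an Illumina instrument, per the labels. The deposited values are FPKM per RefSeq transcript, which the authors made with TopHat2 and Cufflinks against the mouse build mm10, per the submitters' processing notes, with no versions given in the sources used here. The deposited tables also list for each transcript a read coverage, the upper limit of the FPKM confidence interval and a status flag, per the file headers. Each of the 19 tables held the same 34535 transcripts of 24343 gene symbols. No counts were among the values, so tests were made on a log scale, and every log2 difference is on the log2(FPKM + 1) scale, which understates the change of genes with low values.

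FPKM were summed over the transcripts of each gene symbol. A gene was tested in a population when at least 3 of its libraries reached 1 FPKM. Genes with an estimate of failed or capped status were left out of the population concerned, a filter chosen after the status column had been seen (Amd1, Amd2, Ly6e, Tgm4, 9530053A07Rik, Filip1l and Cmss1). Each population was fitted separately with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), with the 2 groups as the only term and the difference taken as Lgr5-DTR minus wild type. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. The difference between populations was tested in limma as an interaction, over genes tested in both. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and statmod 1.5.0 served the correlation estimates.

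Gene lists, tests, named-gene rule and alternatives were fixed before the data were examined. There were 36 lists of genes, of which 1 had no member in the tables. A list with at least 5 tested members was compared with the other genes by limma's camera, with its preset correlation of 0.01, and 32, 31 and 31 lists were tested in stromal, basal and luminal cells. Camera with an estimated correlation and fry were run as alternatives. For lists of cell type markers, each library's mean log2(FPKM + 1) was compared between populations by exact permutation. The named genes of each population were the 10 with the largest positive and the 10 with the largest negative change among called genes with a group mean of at least 5 FPKM and no overlap between the groups, filled up to 5 per direction with the smallest unadjusted p. To these were added up to 4 members per list with the smallest p, and for each pair of populations the 5 genes with the smallest interaction p. Predicted genes and pseudogenes were skipped in the first part, and Lgr5 was given in each population. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

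The depth of each library was read from the deposited coverage times transcript length, which gave 5.26 to 9.38 gigabases. Because these are not counts, no counting interval was computed, and the precision comes from the replicates. The median SE of a log2 difference was 0.258 in stromal, 0.196 in basal and 0.228 in luminal cells. The tests were checked on simulated data built from the real means and spread. Each gene was drawn independently, so deviations that many genes of a library share were absent, and the shares below may be too favourable. Only genes with a mean above 2 on the log2(FPKM + 1) scale were changed, so recovery at lower levels was not measured. In stromal cells (10440 genes run) a simulated log2 change of 1 was recovered in 39% of changed genes and a change of 2 in 98%, in basal cells (9544 genes) in 82% and 97%, and in luminal cells (10351 genes) in 71% and 98%. The share of false calls was 9.87%, 8.21% and 6.63%, above the nominal 5 in 100. For the interaction between stromal and basal cells (8754 genes) the shares recovered were 17.0% and 95.6%, between stromal and luminal cells (9049 genes) 12.4% and 87.6%, and between basal and luminal cells (8910 genes) 31.6% and 92.9%.

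The tables fell into 2 sets by their status and upper-limit columns, for a reason not given in the sources used here. In 7 libraries, 424 transcripts each carried a low-data status and 2551 to 3111 transcripts had an FPKM above their own upper limit, while the other 12 had 0 of either. These 7, called the processing set, held 2 Lgr5-DTR and 1 wild type basal libraries, 1 and 2 luminal libraries, and 1 Lgr5-DTR stromal library. A fit with this set as a covariate was added after it was seen. Apart from this fit and the filter on failed or capped status, the status and upper-limit columns entered no test. Coverage entered no test. Cufflinks divides reads between overlapping transcripts by estimation, and an FPKM of exactly 0 can be a failed or one-sided division, so such genes are described as listed at 0, and near-identical or overlapping genes as uncertain.

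Alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, TMM scaling (trims of 30% and 5%, own implementation on the FPKM columns), quantile normalization, array weights, 1 fit of all 19 libraries, a block for the sample number of the labels, empirical Bayes without the robust step, and each library left out in turn. Estimates that had failed were also put back, and genes listed at 0 in a whole group were also left out. The reference annotation that was at hand was not used here.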

Results

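Gene expression was measured by RNA sequencing in basal, luminal and stromal cells that were isolated by flow sorting from the anterior lobes of mouse prostates. Lgr5-DTR mice carry a diphtheria toxin receptor at Lgr5, a gene for an R-spondin receptor that amplifies Wnt signalling, so that injected toxin kills the cells that express it. The toxin-treated Lgr5-DTR animals gave 3 basal, 3 luminal and 4 stromal libraries, and wild type control animals gave 3 libraries of each population. The design is meant to ask which transcripts change in each population once the Lgr5-expressing stromal cells are removed. Removal of the cells was not itself measured here. The 19 libraries held 5.26 to 9.38 gigabases aligned on annotated transcripts (median 7.73), and 9209 to 10819 genes reached 1 FPKM, a value scaled to transcript length and to the number of mapped fragments. Of the 19 libraries, 7 spread over 5 of the 6 groups carried status entries and upper limits of a kind that the other 12 lacked (the processing set below), too few per group for a comparison within that set. Genotype, toxin treatment and the source of the animals change together between the groups, because the labels record another breeder for the wild type mice and do not say whether those mice received toxin. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

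Lgr5 transcripts were nearly absent from the Lgr5-DTR stromal libraries. The receptor sits at Lgr5 itself, so this fall cannot tell loss of the cells from a change of the Lgr5 allele. Lgr5 (NM_010195) lies on chromosome 10 at 115450314 to 115587780 of mm10, and its annotated span overlaps 1 other gene. It measured 0.916 ± 0.338 FPKM (SD, n = 4) in Lgr5-DTR stromal cells and 44.2 ± 29.0 FPKM (SD, n = 3) in wild type stromal cells, a ratio of 48.2 between the wild type and Lgr5-DTR means. Every Lgr5-DTR library, at 0.501 to 1.32 FPKM, lay below every wild type library, at 25.8 to 77.6 FPKM (exact two-sided permutation p = 0.0286, the smallest that the 35 splits allow). In luminal cells Lgr5 was at 0.612 ± 0.0585 FPKM (SD, n = 3) against 1.82 ± 0.242 FPKM (SD, n = 3) in wild type, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. In basal cells the values were 0.862 ± 0.524 and 0.780 ± 0.106 FPKM (SD, n = 3 each, exact two-sided permutation p = 1).

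Marker transcripts separated the sorted populations in the wild type libraries. On the log2(FPKM + 1) scale the 20 fibroblast markers averaged 8.02 ± 0.06 (SD, n = 3) in stromal cells against 1.75 in basal and 2.15 in luminal cells (exact two-sided permutation p = 0.0119, the smallest that the 84 splits allow). The 20 basal markers averaged 6.20 ± 0.09 (SD, n = 3) in basal cells against 2.58 in luminal and 1.79 in stromal cells (exact permutation p = 0.0119). The 17 luminal markers averaged 7.52 ± 0.14 (SD, n = 3) in luminal cells, 5.42 in basal and 2.98 in stromal cells (exact permutation p = 0.0238). Smooth muscle, endothelial, lymphocyte and pericyte markers were also highest in the stromal libraries, so that 7 of 10 lists were highest in the population they were assigned to, past the threshold. The other 3 lists had been assigned to the stromal sort but were highest in luminal cells, where every wild type library lay above all other wild type libraries. The exact p given for them compares the stromal libraries with all others and does not measure the luminal excess. Schwann cell markers averaged 2.90 in wild type luminal cells, 0.77 in stromal and 0.93 in basal cells (exact permutation p = 0.0833). Erythrocyte markers averaged 2.82 in luminal cells (exact permutation p = 0.274) and macrophage markers 1.66 (exact permutation p = 0.964). Without wild type stromal replicate 1, 4 lists passed.

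In stromal cells the genes that changed were nearly all lower in the Lgr5-DTR libraries, and 9 of 20 fibroblast markers were among them. C7, a complement component, fell from 115 ± 37.7 FPKM (SD, n = 3) in wild type to 10.3 ± 2.10 FPKM (SD, n = 4), and Dpt, which encodes the matrix protein dermatopontin, fell from 278 ± 30.2 to 48.4 ± 16.4 FPKM. Cxcl12, a chemokine of mesenchymal cells, fell from 384 ± 181 to 76.9 ± 5.01 FPKM, and Postn, which encodes the matrix protein periostin, fell from 39.0 ± 5.36 to 7.40 ± 2.50 FPKM. With limma and Benjamini-Hochberg adjustment, 7 genes were higher and 118 lower among the 10689 tested. In each of those 125 genes all 4 Lgr5-DTR libraries lay on the same side of all 3 wild type libraries. Such separation held in 1196 genes in all, 11.2% of those tested, where chance gives 5.71%. At an unadjusted p under 0.05 there were 1230 genes.

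The stromal genes with the steepest falls included transporters, regulators and secreted proteins as well as Lgr5 itself, at -4.40 on the log2 scale (SE 0.35, limma adjusted p = 0.000318). Aqp1, a water channel, changed by -3.77 (SE 0.35, adjusted p = 0.000929), from 32.9 ± 20.6 FPKM in wild type to 1.26 ± 0.503 FPKM. The tetraspanin Tspan8 changed by -3.61 (SE 0.44, adjusted p = 0.0026) and C7 by -3.34 (SE 0.26, adjusted p = 0.000318). Pdlim3, which encodes a protein that binds the actin cytoskeleton, changed by -3.13 (SE 0.41, adjusted p = 0.00437). Osr1, a transcription factor of embryonic mesenchyme, changed by -2.89 (SE 0.34, adjusted p = 0.00216), from 31.4 to 3.35 FPKM. The cadherin Cdh13 changed by -2.76 (adjusted p = 0.00114), Stmn4 of the stathmin family by -2.64 (adjusted p = 0.00124), Dpt by -2.56 (adjusted p = 0.00144) and Ptgds, a prostaglandin D synthase, by -2.54 (adjusted p = 0.00758). Among the 7 higher genes, Pla2g2e, a secreted phospholipase, rose by 1.70 (SE 0.36, adjusted p = 0.0498), Nnat by 1.63 (SE 0.31, adjusted p = 0.0289) and Nipal1 by 1.17 (SE 0.24, adjusted p = 0.0453). Igfbp3, which encodes a protein that binds insulin-like growth factors, was at 929 against 463 FPKM and did not pass (log2 0.98, adjusted p = 0.0666), nor did the peptide hormone gene Ucn2 (log2 0.91, adjusted p = 0.0675). Nnat, C3, Fgf7, Tagln and Cnn1 overlap another annotated gene, so their FPKM are uncertain.

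Among the gene lists, the 20 fibroblast markers had 9 members lower and none higher, or 17 lower and 2 higher when adjusted over the list alone. Their median was -0.83 relative to that of all genes, and limma's camera placed the list below other genes (adjusted p = 3.17e-13, but adjusted p = 0.28 with an estimated correlation). Besides Dpt, the tetranectin gene Clec3b changed by -2.04 (SE 0.29, adjusted p = 0.00617), the actin-severing gelsolin gene Gsn by -1.43 (SE 0.20, adjusted p = 0.00617) and the complement gene C3 by -1.66 (SE 0.25, adjusted p = 0.00943). Of the 31 extracellular matrix genes, 3 were lower (6 lower and 1 higher when adjusted over the list alone). They were Postn at -2.29 (SE 0.27, adjusted p = 0.00216), the fibronectin gene Fn1 at -1.37 (SE 0.21, adjusted p = 0.0107) and the collagen gene Col14a1 at -1.35 (SE 0.25, adjusted p = 0.0254). Camera placed the list lower (adjusted p = 0.015, adjusted p = 0.665 with an estimated correlation). Of 15 markers of periurethral and niche mesenchyme, 3 were lower over all genes and when adjusted over the list alone, namely Lgr5, Osr1 and Sult1e1, an estrogen sulfotransferase, at -1.65 (SE 0.33, adjusted p = 0.041). That list holds Lgr5, the targeted gene, and its median was only -0.19 relative to that of all genes. Its camera adjusted p was 0.0214, and adjusted p = 0.665 with an estimated correlation. It was not tested without Lgr5, so its result is not separate from the fall of Lgr5. Of the 19 stromal growth factors, Cxcl12 at -2.21 (SE 0.27, adjusted p = 0.00243) and Fgf7, a fibroblast growth factor that acts on epithelium, at -1.59 (SE 0.27, adjusted p = 0.0183) were lower. When adjusted over the list alone 2 were lower and 1 higher, and the list did not pass as a whole (camera adjusted p = 0.0708).

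Interferon response genes (28 tested, median 0.42 relative to all genes, camera adjusted p = 2.67e-06) and macrophage markers (12 tested, 0.48, adjusted p = 1.7e-05) lay higher as groups in stromal cells. So did smooth muscle markers (16 tested, 0.46, camera adjusted p = 0.0141), ERK pathway target genes (19 tested, 0.30, adjusted p = 0.0141) and Wnt target genes (14 tested, 0.18, adjusted p = 0.0249). With an estimated correlation the macrophage and ERK lists had adjusted p = 0.601 and the other 3 had adjusted p = 0.665. No member of these 5 lists passed over all genes. When adjusted over the list alone, 1 macrophage marker was higher, 3 smooth muscle markers were higher and 1 lower, and none of the others passed. The values included Lyz2, the macrophage lysozyme, at 1.15 (limma adjusted p = 0.132), Tagln, a smooth muscle actin-binding protein, at 1.01 (adjusted p = 0.117), and the ERK phosphatase genes Dusp6 at 0.73 (adjusted p = 0.261) and Dusp5 at 0.67 (adjusted p = 0.266). Immediate early genes (21 tested, median -0.46 relative to all genes, adjusted p = 0.00503) and heat shock genes (15 tested, -0.49, adjusted p = 0.015) lay lower, with adjusted p = 0.799 and 0.718 with an estimated correlation. When adjusted over the list alone, 4 immediate early genes and no heat shock genes were lower. Of the 32 lists tested, 10 passed camera with the preset correlation and 0 passed with an estimated correlation, where the lowest adjusted p was 0.28 and 1 list had an unadjusted p under 0.05. Fry called 1 list, the fibroblast markers (adjusted p = 0.0138). The count past camera was 6 without Lgr5-DTR replicate 4 and 15 without Lgr5-DTR replicate 1. The YAP and TAZ target genes of mechanical signalling had 1 member lower of 23 (2 lower and 1 higher when adjusted over the list alone, camera adjusted p = 0.527). Focal adhesion, EGF receptor, inflammatory, hypoxia and pericyte lists did not pass, and their median, mean and test differed in sign.

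The count of lower stromal genes rested partly on wild type replicate 3, the highest wild type library in 89 of the 118 lower genes against 43.1% of all tested genes. Without it 2 genes were higher and 43 lower. Without Lgr5-DTR replicate 4 the counts were 43 and 186, and without Lgr5-DTR replicate 3, the highest in 6 of the 7 higher genes, they were 3 and 46. Without wild type replicate 1 the counts were 4 and 47, without wild type replicate 2 they were 3 and 71, and without Lgr5-DTR replicates 1 and 2 in turn they were 2 and 67, and 4 and 77. Of the 22 named genes past the threshold, 13 passed with each of the 7 libraries left out in turn. Pla2g2e, Nnat, Nipal1, Sult1e1, Fgf7 and Col14a1 were each lost without 4 or more of them, Fn1 without Lgr5-DTR replicate 3 or wild type replicate 1, C3 without wild type replicate 1 and Ptgds without wild type replicate 3. With the processing set as a covariate 3 genes were again higher and 46 lower. Lgr5-DTR replicate 3 is the only stromal library in that set, so this fit in effect leaves it out and cannot test the set. TMM and quantile scaling moved the median of all stromal genes by 0.10 and 0.11 on the log2 scale, and 73 and 68 genes were then lower.

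**Figure D1:**
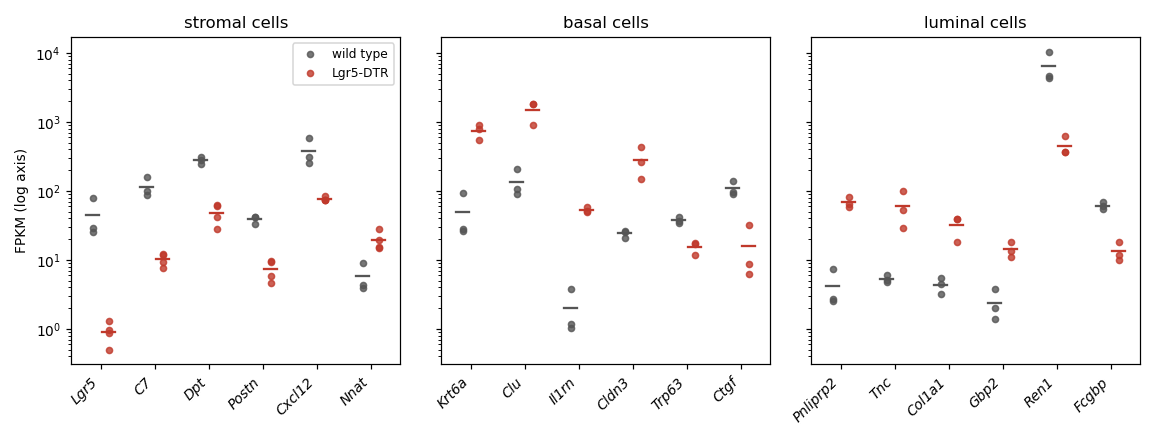
FPKM of 6 named genes in each of the 3 sorted populations on a log axis, with wild type libraries as grey points, Lgr5-DTR libraries as red points and group means as bars. In stromal cells Lgr5 lay at 0.501 to 1.32 FPKM in Lgr5-DTR and at 25.8 to 77.6 FPKM in wild type, and in basal cells Il1rn measured 52.7 FPKM in Lgr5-DTR against 2.01 FPKM in wild type on average.

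Among the genes called in basal cells of Lgr5-DTR mice were higher keratin 6, inflammatory and luminal-type transcripts and lower cholesterol synthesis, matrix and contractile transcripts, and no list passed camera with an estimated correlation. Krt6a, a keratin of activated epithelium, rose from 49.6 ± 38.6 to 739.8 ± 180.0 FPKM (SD, n = 3 each), and Il1rn, the antagonist of the interleukin 1 receptor, rose from 2.01 ± 1.57 to 52.7 ± 4.83 FPKM. Cldn3, a tight junction claudin, rose from 24.3 ± 3.00 to 280.3 ± 146 FPKM. Trp63, the transcription factor that maintains basal cells, fell from 37.8 ± 3.94 to 15.4 ± 3.13 FPKM, and Ctgf, a secreted matricellular protein, fell from 109 ± 27.1 to 15.8 ± 14.3 FPKM. With limma and Benjamini-Hochberg adjustment 634 genes were higher and 435 lower among 9755 tested, each with all 3 Lgr5-DTR libraries on the same side of all 3 wild type libraries. The groups did not overlap in 3036 genes, 31.1% of those tested, where chance gives 10%, and 2703 genes had an unadjusted p under 0.05.

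The largest rise in basal cells was that of Calcb, which encodes a calcitonin gene-related peptide, at 6.06 on the log2 scale (SE 0.69, adjusted p = 0.00223). The retinaldehyde dehydrogenase gene Aldh1a3 rose by 4.89 (SE 0.61, adjusted p = 0.00304). Among the other rises were Dmkn at 5.57 (SE 0.55, adjusted p = 0.00158), Sbsn at 3.85 (SE 0.43, adjusted p = 0.00215) and Krt6a at 4.09 (SE 0.45, adjusted p = 0.00206). Further rises were those of Il1rn at 4.27 (SE 0.31, adjusted p = 0.000575), the cytochrome P450 gene Cyp2b10 at 4.20 (SE 0.54, adjusted p = 0.00322), the chemokine gene Cxcl3 at 4.01 (SE 0.45, adjusted p = 0.00221) and the annexin gene Anxa8 at 3.94 (SE 0.47, adjusted p = 0.00284). Among the falls were Ren1, a renin, at -3.10 (SE 0.71, adjusted p = 0.0292), Ctgf at -3.01 (SE 0.50, adjusted p = 0.00922), the matrix protein gene Sparc at -2.72 (SE 0.50, adjusted p = 0.0134) and Sprr2f, a cornified envelope gene, at -2.69 (SE 0.30, adjusted p = 0.00179). Ren1 averaged 62.2 FPKM in wild type and 7.28 in Lgr5-DTR basal cells, against 6410 and 451 FPKM in luminal cells. Its basal fall cannot be told apart from luminal RNA carried into the basal sort. Spry4, an inhibitor of receptor tyrosine kinase signalling that ERK activity induces, fell from 40.3 to 6.03 FPKM (log2 -2.66, SE 0.36, adjusted p = 0.00401). The peptidase gene Scpep1 was at -2.56 (adjusted p = 0.0125). Taf10 was listed at 0 in all 3 Lgr5-DTR libraries and at 127 to 176 FPKM in wild type, and Cox16 was listed at 0 in Lgr5-DTR and at 9.13 to 15.9 FPKM in wild type. Both overlap other genes and are uncertain, as are Anxa8, Fdft1, Ren1, Scpep1, Cldn3, Tagln, Timp3, Il1a and Mmp7 for the same reason.

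Cholesterol and lipid synthesis genes fell in 8 of 20 members in basal cells and rose in 1 (11 lower and 1 higher when adjusted over the list alone). Among them were Idi1 at -2.66 (SE 0.34, adjusted p = 0.00304), Cyp51 at -2.01 (SE 0.27, adjusted p = 0.0033), Hmgcs1 at -1.69 (SE 0.29, adjusted p = 0.00949) and Fdft1 at -3.31 (SE 0.77, adjusted p = 0.031), all enzymes of the sterol pathway. The camera adjusted p of the list was 0.000149, and adjusted p = 0.603 with an estimated correlation. Matrix genes were lower in 9 of 16 (9 lower and 2 higher when adjusted over the list alone, camera adjusted p = 0.00227, adjusted p = 0.424 with an estimated correlation). Timp3, an inhibitor of metalloproteinases, was at -1.36 (SE 0.19, adjusted p = 0.00436) and the protease gene Adamts1 at -1.20 (SE 0.17, adjusted p = 0.00386). Smooth muscle markers were lower in 5 of 11 (6 when adjusted over the list alone, camera adjusted p = 0.00101, adjusted p = 0.424 with an estimated correlation). Tagln was at -1.84 (SE 0.21, adjusted p = 0.00179) and the myosin light chain gene Myl9 at -1.20 (SE 0.21, adjusted p = 0.00894). Fibroblast markers were lower in 4 of 7, or in 5 with 1 higher when adjusted over the list alone, and had a camera adjusted p of 0.0201 (adjusted p = 0.603 with an estimated correlation). Dcn, the proteoglycan decorin, was at -1.01 (SE 0.27, adjusted p = 0.0446). Stromal growth factors were lower in 4 of 12 (5 when adjusted over the list alone). The heparin-binding factor Ptn was at -1.21 (SE 0.19, adjusted p = 0.00595) and Cxcl12 at -1.52 (SE 0.36, adjusted p = 0.0315). That list had a camera adjusted p of 0.0177, and adjusted p = 0.603 with an estimated correlation.

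Immediate early genes were lower in 3 of 21 basal members (4 when adjusted over the list alone). The stress-induced factor Atf3 was at -1.73 (SE 0.36, limma adjusted p = 0.0191) and Zfp36, which encodes a protein that destabilises messenger RNA, at -1.02 (SE 0.17, adjusted p = 0.00857). The list had a camera adjusted p of 0.00291, and adjusted p = 0.651 with an estimated correlation. Hypoxia and glycolysis genes were lower in 4 of 20 (7 when adjusted over the list alone). Adm, which encodes the peptide adrenomedullin, was at -1.05 (adjusted p = 0.00764) and the hexokinase gene Hk2 at -0.65 (adjusted p = 0.0392). That list had a camera adjusted p of 0.00291, and adjusted p = 0.603 with an estimated correlation. Prostate secretory proteins were lower in 1 of 8, the same count as when adjusted over the list alone (camera adjusted p = 0.0445, adjusted p = 0.651 with an estimated correlation).

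Some luminal and progenitor-type epithelial genes were higher in Lgr5-DTR basal cells, and neither list passed with an estimated correlation. In wild type the progenitor list already averaged 6.08 to 6.80 on the log2(FPKM + 1) scale in basal libraries, against 3.78 to 4.79 in luminal libraries. Krt8 and Krt18 of the luminal list averaged 1318 and 2255 FPKM in wild type basal cells, against 1670 and 2565 in luminal cells. A change within basal cells cannot be told apart here from a changed share of other epithelial cells in the basal sort. Markers of luminal progenitors were higher in 6 of 14 and lower in 1, the same when adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.603 with an estimated correlation). Clu, which encodes the chaperone clusterin, rose from 134 to 1500.0 FPKM (log2 3.51, SE 0.37, adjusted p = 0.00167). Luminal markers were higher in 6 of 15 (7 higher and 1 lower when adjusted over the list alone). Cldn3 was at 3.34 (SE 0.34, adjusted p = 0.00162) and the keratin gene Krt19 at 1.31 (SE 0.22, adjusted p = 0.0088). That list had a camera adjusted p of 0.03, and adjusted p = 0.603 with an estimated correlation. Junction genes were higher in 7 of 26 and lower in 1 (9 and 2 when adjusted over the list alone, camera adjusted p = 0.00605, adjusted p = 0.603 with an estimated correlation). The polarity gene Pard6b was at 1.49 (SE 0.14, adjusted p = 0.0011) and the desmosomal plakophilin gene Pkp3 at 1.04 (SE 0.14, adjusted p = 0.00304). The basal markers themselves were split, with 2 higher and 3 lower of 17 (3 and 3 when adjusted over the list alone, camera adjusted p = 0.957). Trp63 changed by -1.26 (SE 0.18, adjusted p = 0.00448) and Krt15 by -0.70 (SE 0.16, adjusted p = 0.0252). The median, mean and test of the basal markers and of the ribosomal proteins differed in sign.

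Inflammatory genes were higher in 7 of 22 and lower in 2 in basal cells (10 and 4 when adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.603 with an estimated correlation). The cytokine gene Il1a was at 2.69 (SE 0.38, limma adjusted p = 0.00495) and the NF-kB regulator gene Nfkbiz at 1.5 (SE 0.15, adjusted p = 0.0015). Macrophage markers were higher in 5 of 10 (8 when adjusted over the list alone), at low levels. Ctss, a lysosomal protease, was at 3.14 against 0.174 FPKM (log2 1.77, SE 0.26, adjusted p = 0.00472) and Lyz2 rose by 1.21 (SE 0.22, adjusted p = 0.0113). The macrophage list had a camera adjusted p of 0.00101, and adjusted p = 0.603 with an estimated correlation. Markers of epithelial to mesenchymal transition were higher in 2 of 8 (3 when adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.603 with an estimated correlation). They were led by the metalloproteinase gene Mmp7 at 3.06 (SE 0.31, adjusted p = 0.00162), which epithelial cells also make. Endothelial markers had no member past the threshold among 11, over all genes or when adjusted over the list alone (camera adjusted p = 0.00986, adjusted p = 0.603 with an estimated correlation), and Plvap was at 1.01 (adjusted p = 0.0554). Of the 18 ERK pathway target genes, 1 was higher and 3 lower (2 and 7 when adjusted over the list alone, camera adjusted p = 0.147). Of the 23 YAP and TAZ target genes, 3 were higher and 5 lower, the same when adjusted over the list alone (camera adjusted p = 0.375), and Ctgf was among those that fell. EGF receptor ligands went both ways, with Btc at 1.89 (SE 0.23, adjusted p = 0.00223) and Hbegf at -0.97 (SE 0.20, adjusted p = 0.0174), and in the list of 10 there were 2 higher and 1 lower (4 and 1 when adjusted over the list alone, camera adjusted p = 0.113).

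Of the 31 lists tested in basal cells, 15 passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.424 and 2 lists had an unadjusted p under 0.05, while fry called 3. The basal counts depended on single libraries. Lgr5-DTR replicate 1 was the lowest of its group in 355 of the 634 higher genes and the highest in 325 of the 435 lower genes, and without it 992 genes were higher and 1272 lower. Without Lgr5-DTR replicate 2 the counts were 226 and 124, without replicate 3 they were 367 and 194, without wild type replicate 2 they were 221 and 116, and without wild type replicate 3 they were 225 and 131. Of the 48 named genes past the threshold, 34 passed with each of the 6 libraries left out in turn. The other 14 were lost without wild type replicate 2. Among them Fdft1, Ren1, Krt15, Cxcl12, Dcn, Ctgf, Sparc, Scpep1, Lyz2, Zfp36, Atf3, Hbegf and Hk2 were each also lost without at least 1 further library. With the processing set as a covariate 478 genes were higher and 293 lower.

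Among the genes called in luminal cells of Lgr5-DTR mice were higher matrix, interferon and glial transcripts and lower prostate secretory transcripts. None of these lists passed camera with an estimated correlation, and every gene named from them lost its call without wild type replicate 3. The lipase gene Pnliprp2 rose from 4.23 ± 2.79 to 68.7 ± 12.4 FPKM (SD, n = 3 each), and Tnc, which encodes the matrix protein tenascin C, rose from 5.36 ± 0.700 to 60.8 ± 35.9 FPKM. Ren1 fell from 6410.2 ± 3353 to 451 ± 156 FPKM, and Fcgbp, a mucin-like secreted protein, fell from 60.9 ± 6.83 to 13.4 ± 4.22 FPKM. With limma and Benjamini-Hochberg adjustment 276 genes were higher and 54 lower among 10524 tested, each with all 3 Lgr5-DTR libraries on the same side of all 3 wild type libraries. The groups did not overlap in 2848 genes, 27.1% of those tested, where chance gives 10%, and 2386 genes had an unadjusted p under 0.05. The median of all luminal genes lay at 0.10 on the log2 scale, and TMM and quantile scaling moved it by -0.14 and -0.15. Higher genes made up 83.6% of the calls, against 54.2% under TMM scaling (218 higher and 184 lower) and 66.8% under quantile scaling (143 and 71).

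Besides Pnliprp2 at 3.84 (SE 0.33, adjusted p = 0.00201), the luminal genes with the largest rises were of several kinds. The semaphorin gene Sema4f rose by 3.77 (SE 0.41, adjusted p = 0.00485), the laminin-binding integrin gene Itga7 by 3.64 (SE 0.43, adjusted p = 0.00767), Ucn2 by 3.57 (SE 0.36, adjusted p = 0.00318) and Clu by 3.54 (SE 0.67, adjusted p = 0.0459). Tgfbi, a matrix protein gene induced by TGF-beta, rose by 3.39 (SE 0.44, adjusted p = 0.00882), the adaptor gene Dok4 by 3.31 (SE 0.40, adjusted p = 0.00767), the fibroblast growth factor gene Fgf5 by 3.21 (SE 0.31, adjusted p = 0.00309) and the collagen gene Col5a2 by 3.13 (SE 0.42, adjusted p = 0.00998). Defa20, at 3.23 (adjusted p = 0.0136), belongs to a family of near-identical defensin genes and is uncertain. Apart from genes listed at 0, the falls were led by Ren1 at -3.76 (SE 0.36, adjusted p = 0.00318) and Ren2 at -3.67 (SE 0.37, adjusted p = 0.00485), near-identical renin genes whose reads cannot be assigned with certainty. Fcgbp changed by -2.14 (SE 0.22, adjusted p = 0.00318), the metallothionein gene Mt3 by -1.80 (SE 0.19, adjusted p = 0.00318), the ion channel gene Mcoln2 by -1.60 (SE 0.23, adjusted p = 0.00998) and Coch by -1.60 (SE 0.27, adjusted p = 0.0199). Toporsos, Emc9, Cmc1 and Tm7sf2 were listed at 0 in all 3 Lgr5-DTR luminal libraries, against 48.8 to 79.1, 13.3 to 14.1, 8.58 to 9.64 and 6.81 to 7.06 FPKM in wild type. Each of these 4 overlaps another gene and is uncertain, and Itga7, Dok4, Itga5, Cxcl10, Gbp2 and Rpl32 overlap another gene as well.

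Matrix genes rose in 10 of 22 luminal members and fell in none (18 rose when adjusted over the list alone). Their median was 1.20 relative to all genes, and camera placed the list above other genes (adjusted p = 1.92e-10, adjusted p = 0.374 with an estimated correlation). Tnc rose by 3.12 (SE 0.38, adjusted p = 0.00817), Sparc by 1.47 (SE 0.26, adjusted p = 0.023) and the basement membrane collagen gene Col4a1 by 1.18 (SE 0.20, adjusted p = 0.0207). Interferon response genes rose in 10 of 27 (18 when adjusted over the list alone, median 0.66 relative to all genes, camera adjusted p = 3e-10, adjusted p = 0.241 with an estimated correlation). Among them were the guanylate-binding proteins Gbp2 at 2.20 (SE 0.29, adjusted p = 0.00817) and Gbp3 at 2.01 (SE 0.27, adjusted p = 0.00817) and the immunoproteasome gene Psmb8 at 1.53 (SE 0.19, adjusted p = 0.00767). Prostate secretory proteins fell in 5 of 9 and rose in 1, the same when adjusted over the list alone (median -1.25, camera adjusted p = 0.000127, adjusted p = 0.241 with an estimated correlation). Azgp1 changed by -1.39 (SE 0.26, adjusted p = 0.0252) and 9530003J23Rik by -2.65 (SE 0.34, adjusted p = 0.00817), while the beta-defensin gene Defb50 rose by 1.80 (SE 0.34, adjusted p = 0.0278). 9530003J23Rik lies within 20 Mb of Lgr5 on chromosome 10, so an effect of that locus stays open for its fall.

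Some glial and macrophage markers were also called higher in the luminal libraries, and neither list passed camera with an estimated correlation. Schwann cell markers rose in 3 of 10 (8 when adjusted over the list alone, median 1.04 relative to all genes, camera adjusted p = 0.000348, adjusted p = 0.436 with an estimated correlation). The glial transcription factor gene Sox10 was at 38.3 against 7.01 FPKM (log2 2.17, SE 0.39, limma adjusted p = 0.0278) and the neurotrophic receptor gene Gfra3 at 1.91 (SE 0.40, adjusted p = 0.0446). Macrophage markers rose in 2 of 13 (5 when adjusted over the list alone, median 1.15, camera adjusted p = 0.0032, adjusted p = 0.436 with an estimated correlation). Ctss was at 2.34 (SE 0.44, adjusted p = 0.0298) and Lyz2 at 2.37 (SE 0.45, adjusted p = 0.0354). Sox10, Tnc, Ctss and Lyz2 were all highest in Lgr5-DTR replicate 1, at 64.0, 99.8, 24.7 and 44.8 FPKM, and lowest of that group in replicate 2, at 20.3, 29.2, 6.58 and 11.1 FPKM. Pericyte markers rose in 2 of 8 (3 when adjusted over the list alone, camera adjusted p = 0.0151, adjusted p = 0.436 with an estimated correlation). Fibroblast markers rose in 4 of 9, the same when adjusted over the list alone, with Col1a1 at 2.56 (SE 0.31, adjusted p = 0.00681), and their list did not pass (camera adjusted p = 0.181). None of the 17 luminal markers passed over all genes (1 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.13).

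Signalling lists lay higher in luminal cells by camera, each without passing under an estimated correlation. The inflammatory list had 3 of 21 higher (7 when adjusted over the list alone, camera adjusted p = 0.000123, adjusted p = 0.436 with an estimated correlation). Nfkbiz was at 2.01 (SE 0.31), the interferon-induced chemokine gene Cxcl10 at 1.77 (SE 0.32) and the monocyte chemokine gene Ccl2 at 1.61 (SE 0.27, limma adjusted p = 0.0158, 0.0243 and 0.019). Growth factors had 2 of 11 higher (5 when adjusted over the list alone, camera adjusted p = 0.00178, adjusted p = 0.241 with an estimated correlation). They were Gdnf, a neurotrophic factor gene, at 2.13 (SE 0.33, adjusted p = 0.0158) and Ptn at 2.11 (SE 0.35, adjusted p = 0.0191). Focal adhesion and actomyosin genes had 2 of 37 higher (4 when adjusted over the list alone, camera adjusted p = 0.000348, adjusted p = 0.436 with an estimated correlation). They were the fibronectin-binding integrin gene Itga5 at 2.04 (SE 0.27, adjusted p = 0.00817) and the GTPase gene Rhoc at 1.53 (SE 0.27, adjusted p = 0.021). TGF-beta targets had 2 of 18 higher (9 when adjusted over the list alone, camera adjusted p = 9.21e-06, adjusted p = 0.374 with an estimated correlation). YAP and TAZ targets had 1 of 23 higher (7 when adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.436 with an estimated correlation). ERK pathway targets had 1 of 15 higher, Phlda1 at 0.95 (SE 0.17, adjusted p = 0.0239), and 5 when adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.351 with an estimated correlation). Dusp5 was at 1.00 (adjusted p = 0.0633). EGF receptor ligands had 1 of 9 higher, Btc at 2.65 (SE 0.34, adjusted p = 0.00817), and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0437, adjusted p = 0.436 with an estimated correlation).

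Further luminal lists past camera were of other kinds. Immediate early genes had 2 of 21 higher (5 when adjusted over the list alone, camera adjusted p = 0.00619, adjusted p = 0.436 with an estimated correlation), with Zfp36 at 0.91 (SE 0.16, limma adjusted p = 0.021). Markers of epithelial to mesenchymal transition had 2 of 9 higher (5 when adjusted over the list alone, camera adjusted p = 0.00896), luminal progenitor markers 1 of 15, which was Clu (4 when adjusted over the list alone, adjusted p = 0.0266), and p53 targets 3 of 24 (3 when adjusted over the list alone, adjusted p = 0.0266). These 3 lists each had adjusted p = 0.436 with an estimated correlation. Wnt targets had 2 of 13 higher (3 when adjusted over the list alone) without passing as a list (camera adjusted p = 0.0934), and among them the adhesion receptor gene Cd44 rose by 1.78 (SE 0.28, adjusted p = 0.0164). Ribosomal protein genes (76 tested, median -0.38 relative to all genes, camera adjusted p = 6.41e-11) and oxidative phosphorylation genes (37 tested, -0.37, adjusted p = 3.84e-06) lay lower, each with adjusted p = 0.436 with an estimated correlation. No member of these 2 lists passed, over all genes or when adjusted over the list alone, and Rpl32 was at -0.57 (adjusted p = 0.174) and the respiratory complex gene Ndufa2 at -0.68 (adjusted p = 0.0782). Unfolded protein response and secretory pathway genes had 1 of 28 lower (3 when adjusted over the list alone, camera adjusted p = 9.21e-06, adjusted p = 0.241 with an estimated correlation). It was Herpud1 at -0.95 (SE 0.19, adjusted p = 0.0292). The androgen response and hypoxia lists did not pass, and their median, mean and test differed in sign.

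Of the 31 lists tested in luminal cells, 20 passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.241 and 4 lists had an unadjusted p under 0.05, while fry called 6. Lgr5-DTR replicate 1 was the highest of its group in 188 of the 276 higher genes, and wild type replicate 2 the highest of its group in 45 of the 54 lower genes. Without wild type replicate 3, 3 genes were higher and 6 lower, and without wild type replicate 2 the counts were 25 and 10. Without Lgr5-DTR replicate 1 they were 118 and 29, without replicate 2 they were 308 and 24, and without replicate 3 they were 660 and 267. Of the 46 named genes past the threshold, 7 passed with each of the 6 libraries left out in turn, namely Pnliprp2, Ren1, Ren2, Toporsos, Emc9, Cmc1 and Tm7sf2. With the processing set as a covariate 488 genes were higher and 262 lower.

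**Figure D2:**
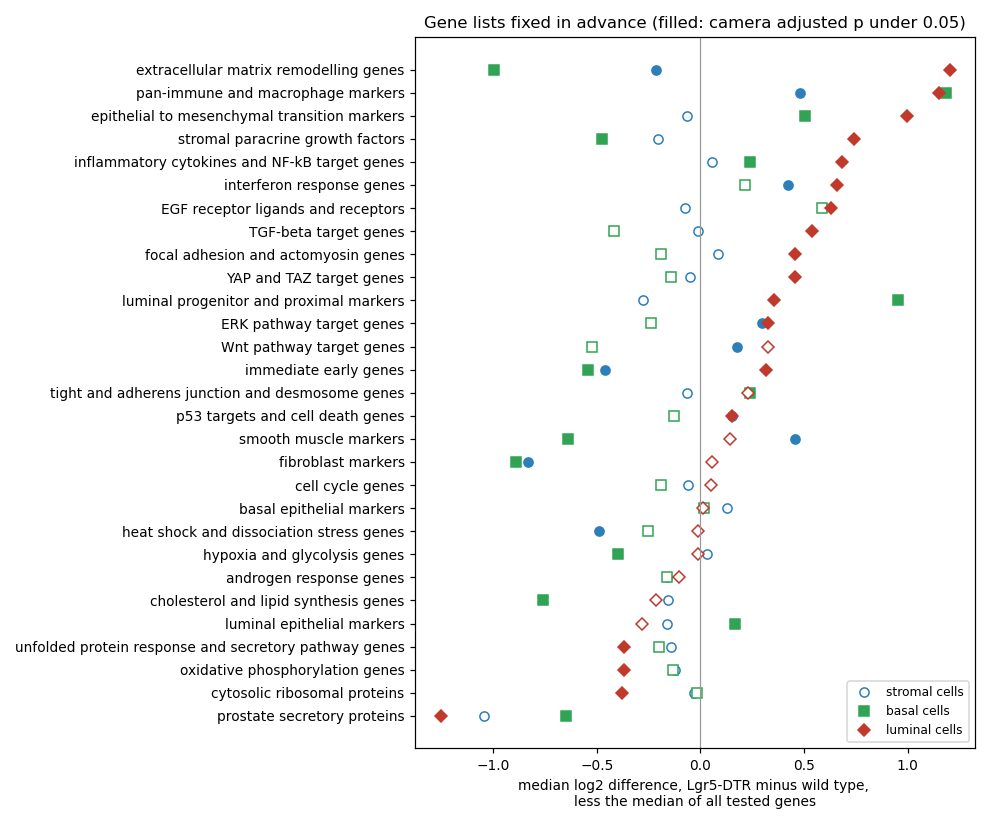
Median log2 difference between Lgr5-DTR and wild type of each gene list tested in all 3 populations, less the median of all tested genes, with a filled symbol where the camera adjusted p was under 0.05. Fibroblast markers lay at -0.83 in stromal cells, and matrix genes at 1.20 in luminal cells. With an estimated correlation 0 lists passed in each population.

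Several genes moved in opposite directions in the 3 populations. Ccdc80, which encodes a secreted matrix protein, changed by -1.94 in stromal cells and by 2.24 in basal and 1.93 in luminal cells, and Postn changed by -2.29 in stromal and 2.51 in luminal cells. The interaction test in limma, with Benjamini-Hochberg adjustment, found that the difference between Lgr5-DTR and wild type itself differed between stromal and basal cells in 268 of 8980 genes, 188 of them more positive in basal cells. Between stromal and luminal cells it differed in 232 of 9255 genes, 225 of them more positive in luminal cells, and between basal and luminal cells in 388 of 9098, 289 of them more positive in luminal cells. The genes with an unadjusted p under 0.05 were 1301, 1246 and 2067. For Ccdc80 the stromal difference less the basal one was -4.19 (adjusted p = 9.67e-05) and the stromal less the luminal -3.88 (adjusted p = 7.26e-05). For Postn the stromal less the luminal difference was -4.80 (adjusted p = 0.000496) and for S1pr3, a receptor gene for sphingosine 1-phosphate, it was -3.79 (adjusted p = 0.000163), from -2.21 in stromal to 1.58 in luminal cells. Cdh13 was at -2.76 in stromal and 1.06 in basal cells (difference -3.82, adjusted p = 4.69e-05), and Dmkn at -1.71 and 5.57 (difference -7.27, adjusted p = 4.69e-05).

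Genes called lower in both stromal and basal cells numbered 11, where independent lists would share 2.41, and as many, 11, were called in opposite directions. Stromal and luminal cells shared 0 lower genes, and 6 were called in opposite directions. Basal and luminal cells shared 56 higher genes against 12.9 for independent lists, and 9 lower genes against 1.42. Ren1 was among the 9, and luminal RNA carried into the basal sort could account for its basal fall. The shared counts also rest on luminal calls, of which 3 higher and 6 lower were left without wild type luminal replicate 3. The titles give libraries of different populations some of the same numbers, and the labels do not say whether these came from the same animals, in which case chance differences would also be shared. Basal and luminal cells moved in opposite directions in 17 genes called in both. These included, as genes chosen after their values were seen, the basement membrane genes Col4a1, Col4a2 and Nid1 as well as Sparc, Ptn and Zfp36. The difference of Zfp36 was -1.02 in basal and 0.91 in luminal cells, and -1.92 between them (interaction adjusted p = 0.00173 by limma). The interaction counts also depended on single libraries. The count between stromal and basal cells was 118 without Lgr5-DTR basal replicate 2, 134 and 135 without wild type basal replicates 3 and 2, and 177 without either Lgr5-DTR basal or stromal replicate 3. Between stromal and luminal cells it was 109 without Lgr5-DTR luminal replicate 1, 127 without wild type luminal replicate 2 or wild type stromal replicate 3, 139 without wild type stromal replicate 1, 144 without wild type luminal replicate 3 and 152 without Lgr5-DTR stromal replicate 3. Between basal and luminal cells it was 787 without Lgr5-DTR basal replicate 1, 140 and 220 without Lgr5-DTR basal replicates 2 and 3, 149 and 143 without wild type basal replicates 2 and 3, 222 without Lgr5-DTR luminal replicate 1, and 174 and 225 without wild type luminal replicates 2 and 3. TMM and quantile scaling lowered the count between stromal and luminal cells to 118 and 76.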

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

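The tests of stromal carry-over, Schwann cells, scaling, fibroblast share, the chromosome segment and overlapping genes were chosen after the results were seen, while the splits of the samples were planned. The count of splits without those that keep or exchange all labels of a population was also chosen after the results were seen.

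The difference between Lgr5-DTR and wild type differed between stromal and basal cells in 268 genes, between stromal and luminal cells in 232 and between basal and luminal cells in 388, by the interaction test in limma. Stromal less basal, the log2 difference was -3.82 for Cdh13, -7.27 for Dmkn, -5.77 for Anxa8, -4.19 for Ccdc80 and 3.13 for Cox16. Stromal less luminal, it was -3.88 for Ccdc80, -3.79 for S1pr3, -3.20 for Tmod1, -4.80 for Postn and -3.63 for Entpd2. Basal less luminal, it was -6.98 for Taf10, 3.56 for Mettl3, -3.20 for Cox16, -2.03 for Pde4b and -1.92 for Zfp36. All of these had interaction adjusted p of 0.00173 or lower. Dividing the libraries of each population in other ways, the 100 splits included 5 with as many genes between stromal and basal cells (268 for the real split, 1463 for the highest other), a share at the threshold. Between stromal and luminal cells 3 of 100 splits gave as many (232, highest other 571) and between basal and luminal cells 3 of 100 (388, highest other 1090), shares under 0.05. The splits other than the real one were random draws that could repeat. The shares were not adjusted for the number of counts tested, so they make chance less likely without excluding it. Some splits keep or exchange all labels of a population and so still carry its real difference. Without them 4 of 89 splits gave as many between stromal and basal cells, 2 of 94 between stromal and luminal and 1 of 82 between basal and luminal cells, so for stromal and basal cells the outcome turns on which splits are counted and chance is left open. Between stromal and basal cells, and between stromal and luminal cells, the highest other split mixed the labels of both populations and called more genes than the real split. The cause was not tested. Between basal and luminal cells it held the labels of both whole, with those of 1 population exchanged.

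Cxcl12 in Lgr5-DTR stromal replicate 1 measured 84.4 FPKM, apart from the other 3 libraries of its group, whose highest was at 75 FPKM and lowest at 73.7 FPKM. It was the only gene of 39 named stromal genes with a library this far apart by Dixon's test, which marks about 1 in 20 groups by chance, and the wild type libraries averaged 384 FPKM.

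In the Lgr5-DTR luminal libraries 10 of 22 matrix genes were called higher, together with 3 of 10 Schwann cell and 2 of 13 macrophage markers. With an estimated correlation none of these lists passed camera (adjusted p = 0.374, 0.436 and 0.436). Some pericyte and fibroblast markers were called higher in the same libraries as well. Against stromal cells carried into the luminal gate, 34 of the 50 most abundant stromal-specific transcripts showed a smaller share of stromal RNA than the least that any called matrix gene needs (3.36%), with a median of 1.59%. The shares were uneven, from -0.76% for Gsn to 13.1% for Apod. They were taken against the mean of the Lgr5-DTR stromal libraries, with the called matrix genes left out of the 50. They therefore argue only against carry-over of average stroma, and carry-over of a subset of stromal cells stays open. Against the scaling of the FPKM values, the list's median stayed at 1.12 or above under TMM and quantile scaling. A larger share of unchanged Schwann cells may contribute and cannot be told apart from a change within luminal cells. Here 3 of 10 matrix genes (Col5a2, Tnc and Postn) rose by more than the Schwann marker that rose most, Sox10, but these are the top genes of the pattern. The medians of the ratios were 1.88 for the matrix genes and 1.21 for the 10 markers on the log2 scale. A larger share of unchanged cells alone would raise markers made only by those cells by a common amount. With each library left out in turn, Sox10 lay at 1.86 to 2.75, Cdh19 at 0.86 to 1.44 and Mbp at 0.03 to 0.30. These values argue against such a share as the only cause of the marker changes, and a part in the matrix rise stays open. A response of luminal cells to the loss of Lgr5-expressing stroma, and an effect of the toxin or of the strain, stay open and were not tested.

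In the Lgr5-DTR stromal libraries 9 of 20 fibroblast markers were called lower, and the list did not pass camera with an estimated correlation (adjusted p = 0.28). Sfrp1 at 0.64 and Apod at 0.72 had 95% intervals above 0. A lower share of all fibroblasts would lower their markers by a common amount, but 7 of 20 markers had a 95% interval that misses the list's median of -0.92, with 3 above it (Pdgfra, Sfrp1 and Apod) and 4 below it (Dpt, Clec3b, Gsn and C3). A chromosome segment carried along with the receptor insertion could place called genes near Lgr5, but 3 of the 118 lower genes (Dcn, Lgr5 and Tspan8) lay within 20 Mb of it and 115 elsewhere. Such a segment therefore cannot account for most of them. Of the genes tested in that window 2.31% were called, against 1.16% elsewhere, so a locus effect stays open for Dcn and Tspan8. It also stays open for genes of that window called in the epithelial populations. Among these, Dcn was lower in basal cells, 9530003J23Rik was lower in basal and luminal cells, and Lyz2 was higher in both. In basal cells 12 of 115 genes in the window were called, against 1057 of 9640 elsewhere. In luminal cells 4 of 125 were called, against 326 of 10399 elsewhere. Loss of a subset of fibroblasts that expressed Lgr5, a change within the remaining ones, and strain or toxin effects stay open as hypotheses.

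Among the tested genes, 20 were listed at 0 in every library of one group of a population, 3 in stromal, 10 in basal and 7 in luminal cells, and 17 of them were called. A candidate explanation is that reads were divided differently between overlapping genes. Of the 20, 17 overlap another annotated gene, against 20.2% of the other tested genes (Fisher's exact p = 1.01e-09), and with the overlapping genes summed, 11 of 16 loci differed by less than 0.5 on the log2 scale. This was tested first on the 9 genes with a mean of at least 5 FPKM in one group, where 7 of 8 summed loci lay within that bound, and then extended to all, where 4 of 8 of the added loci did. A sum can also stay within the bound where the overlapping gene is far more abundant, and the share of each gene in its sum was not computed. A sum within the bound therefore does not by itself show that reads were divided differently. Over all of them the division of reads is left open, also because 5 summed loci still differed and 3 genes overlap no other. Among the 5 was Cox16 in basal cells, whose summed locus differed by -6.20. All 20 are given as uncertain, among them Cox16, Mettl3, Taf10, Cmc1, Emc9, Gldn, Tm7sf2, Tmod1 and Toporsos, the 9 of the first test, with Gldn lacking a summed value.

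In stromal cells 1 of the 35 splits of the libraries gave as many lower genes, the real one (118, highest other 24), which argues against chance for that count. This share is the smallest that 35 splits allow and was not adjusted for the number of counts tested. For higher genes 4 of 35 splits gave as many (7, highest other 37) and for lists 8 of 35 splits (10, highest other 15), so chance is not excluded for either. The split with 37 higher genes exchanged Lgr5-DTR replicate 4 for wild type replicate 2. It kept the other Lgr5-DTR libraries together and may carry part of the real difference, and the cause of its count was not tested. In basal and luminal cells the 10 splits are too few for a share under 0.05. In basal cells 1 split gave as many higher genes (634, highest other 5), 1 split as many lower genes (435, highest other 5) and 1 split as many lists (15, highest other 14). In luminal cells 1 split gave as many higher genes (276, highest other 112), 2 splits as many lower genes (54, highest other 112) and 2 splits as many lists (20, highest other 20).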

How the results depend on the processing

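The tests with the processing set, with failed estimates kept and without genes listed at 0 were chosen after the data were seen. Named genes past the threshold kept it in 258 of 308 comparisons with an alternative in stromal cells, 538 of 624 in basal and 501 of 598 in luminal cells, and none reversed. Named genes that had not passed stayed so in 200 of 238, 9 of 13 and 27 of 39. Counts are given below as higher and lower genes and moved by more than 1.5 times in at least 1 of the 2, and the cause was not tested except where fewer libraries or another set of tested genes is the setting itself. In stromal cells (7 and 118) they were 1 and 35 with no filter, 3 and 72 with a filter of 5 FPKM, 5 and 73 with TMM scaling, 8 and 68 with quantile normalization, 235 and 800 with array weights, 62 and 304 in 1 fit of all 19 libraries and 3 and 46 with the processing set. The stromal fit with the processing set in effect repeats leaving out Lgr5-DTR replicate 3, and the comparisons above count both. Leaving out each library gave 2 (without Lgr5-DTR replicate 1 or wild type replicate 3) to 43 higher (without Lgr5-DTR replicate 4) and 43 (without wild type replicate 3) to 186 lower (without Lgr5-DTR replicate 4), with 6 to 15 lists past camera against 10. In basal cells (634 and 435) they were 310 and 182 with no filter and 2053 and 2032 with array weights. Leaving out each library gave 221 to 992 higher and 116 to 1272 lower, lowest without wild type replicate 2 and highest without Lgr5-DTR replicate 1. In luminal cells (276 and 54) they were 0 and 4 with no filter, 218 and 184 with TMM scaling, 143 and 71 with quantile normalization, 649 and 261 with array weights, 724 and 147 in 1 fit of all 19 libraries and 488 and 262 with the processing set. Leaving out each library gave 3 to 660 higher and 6 to 267 lower, lowest without wild type replicate 3 and highest without Lgr5-DTR replicate 3. Beside the 0 higher luminal genes with no filter, that limma fit had 2947 genes at an unadjusted p under 0.05. Camera with an estimated correlation called 0 lists in each population, where 1, 2 and 4 had an unadjusted p under 0.05, and fry called 1 stromal, 3 basal and 6 luminal lists. Interaction counts were 150 with a filter of 5 FPKM and 457 with a shared source for libraries of the same title number against 268 between stromal and basal cells, 118 with TMM, 76 with quantile normalization and 142 with 5 FPKM against 232 between stromal and luminal cells, and 639 with the shared source against 388 between basal and luminal cells. Leaving out each library gave 118 to 385, 109 to 263 and 140 to 787. The Lgr5 difference in stromal cells, -43.2 FPKM, ranged from -52.4 without wild type replicate 2 to -26.5 without wild type replicate 3, and fewer libraries alone raise the smallest exact p above the threshold. In basal cells it ranged from -0.221 FPKM without Lgr5-DTR replicate 1, where it changed sign, to 0.237 FPKM without Lgr5-DTR replicate 2, past the test in neither. The marker lists past their test ranged from 4 (without wild type stromal replicate 1) to 7 against 7. The sample numbers of the labels gave no pairing that held in all populations. Same-numbered libraries correlated at -0.0457 to 0.486 in stromal, -0.526 to -0.230 in basal and -0.124 to 0.380 in luminal cells. A replicate block on these numbers gave 314 and 727 stromal, 151 and 62 basal and 617 and 138 luminal genes. A library correlated best with its own number in 2 stromal, 0 basal and 1 luminal cases. The 2 stromal cases were at 0.376 and 0.486, against at most 0.0301 and -0.0975 with another number, so a pairing of some stromal libraries is left open. A count-based test and its size factors were not run, because the values are FPKM. At this spread a log2 change of 1 was recovered in 39% of simulated stromal genes, which limits the stromal counts.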

Other observations

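The tests used here are those of the report, and the genes in this part were chosen after their values were seen. Every luminal call given here was lost without wild type luminal replicate 3. In basal cells those of Mt3 and Ptges were each lost without 2 of the 6 libraries and that of 1810011O10Rik without 4, and in stromal cells that of Calca was lost without 5 of the 7.

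Mt1, Mt2 and Mt3, which encode small proteins that bind zinc and copper, were lower in both epithelial populations. Mt1 fell from 4982 ± 906 to 2245 ± 69.8 FPKM in basal cells (SD, n = 3 each, log2 -1.14, limma adjusted p = 0.00637) and from 4149 ± 425 to 1857 ± 210.3 FPKM in luminal cells (log2 -1.16, adjusted p = 0.0191). Mt2 changed by -1.07 in basal (adjusted p = 0.00683) and by -1.09 in luminal cells (adjusted p = 0.019), and Mt3 by -1.20 (adjusted p = 0.0106) and -1.80 (adjusted p = 0.00318). In stromal cells Mt1 was at -0.19 (adjusted p = 0.731), Mt2 at -0.05 (adjusted p = 0.969) and Mt3 at 0.20 (adjusted p = 0.936). Ptges, a prostaglandin E synthase, was also lower in both epithelia, by -0.77 in basal (adjusted p = 0.00921) and -1.0 in luminal cells (adjusted p = 0.0297).

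Among the genes that rose in both epithelia were Anxa1, which encodes an anti-inflammatory annexin, at 2.90 in basal (limma adjusted p = 0.00182) and 1.79 in luminal cells (adjusted p = 0.0149), and the galectin gene Lgals3 at 2.37 (adjusted p = 0.00179) and 2.82 (adjusted p = 0.0217). 1810011O10Rik was higher in all 3 populations, at 2.52 in stromal (adjusted p = 0.00216), 1.43 in basal (adjusted p = 0.017) and 1.31 in luminal cells (adjusted p = 0.0178). Calca, which encodes calcitonin gene-related peptide, changed by -1.33 in stromal cells (adjusted p = 0.0328) and rose by 2.34 in basal cells (adjusted p = 0.0025), next to the rise of the related Calcb in basal cells.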
